A study of Mus musculus with 24 samples.

How the data were processed

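The series holds 24 samples of lineage-negative bone marrow cells of C57BL/6 mice, enriched with a lineage depletion kit per the labels. Peak lists of 22 libraries were used, 10 from ChIP-seq and 12 from ATAC-seq. Some deposited items are not used here. Per the labels the authors used Bowtie, Bowtie2, SICER and MACS2 with the mouse build mm10, without versions or roles, and for the Chd4 set Bowtie and MACS2 only. The ChIP lists as deposited by the authors give islands on a grid of 200 bp with a whole number each, taken here as the read count of the island in its own library, not scaled for depth. That role is inferred from the format and is not stated in the labels. The deposited ATAC lists give only the start and end of each interval, so width takes the place of a score and depth is unknown. The score is the authors' and was used only to rank peaks within a list. Island reads, 6.93 to 14.2 M per H3K4me1 and 20.4 to 27.8 M per PU.1 library, are not library depth.

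For each of 6 comparisons the peaks of its libraries were merged where they overlapped or touched. A region was lost when every reference library and no perturbed library had a peak there, gained in the reverse case, and kept when all had one. Kept regions merge peaks of both groups. In every comparison they are thus wider, and more likely to reach a gene end, partly by construction. The log2 ratio of lost to gained is given beside its range and SD over all pairs of single libraries, where a peak counts when only 1 library of the pair has it. That ratio is of another form, so its SD is not an error of the first. Each count was set beside every other split of the same libraries. Peak number, covered length, share at gene ends and share on X were compared by two-sided exact permutation tests of means, whose smallest p is 0.333 with 2 against 2 and 0.1 with 3 against 3. The labels do not say whether replicates are separate animals or cultures, so these p measure spread between samples.

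Regions were assigned to the nearest of 21900 protein-coding gene spans, since the annotation gave neither strand nor transcription start, and a region within 1 kb of either end of a gene counts as at a gene end. This departs from the planned start sites. The 13 gene lists, fixed in advance, cover erythroid, megakaryocyte, mast cell and basophil, granulocyte, monocyte and macrophage, stem cell, B cell, T and NK cell, stroma and endothelium, ETS family, GATA partner, growth and tumour suppression and housekeeping genes. Of 265 members 264 were matched, 2 by an older symbol, and 0 genes were in more than 1 list. Each list was tested against all other regions by Fisher's exact test, two-sided, for losses among regions held by every reference library and gains among those held by every perturbed library, with Benjamini-Hochberg adjustment over 156 tests. Alternative tests over strata used 5 strata of score or width. Motif tests were not run, as no sequence was at hand.

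Named genes were chosen by a rule fixed in advance: Kdm6a, Smarca4, Chd4, Spi1, Gata1 and Gata2; the 5 genes with most lost and the 5 with most gained regions; the 3 lost and 3 gained regions with the highest score or width in the lowest-numbered replicate; up to 4 genes of each list past 0.05 after adjustment and up to 2 of every other list. Some genes that this rule picks are not analysed here. The joins of Utx and Smarca4 losses were set beside 100 simulated unchanged groups drawn against the shared controls, in strata of width. The effect of Smarca4 gRNA was compared between genotypes by an exact permutation test of pairs of libraries with the same number. Settings tried were the upper 50% of each list, equal list length, 50% cover of a region, autosomes only, each library left out, regions within 50 kb of a gene, strata and same-numbered pairs.

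The rules were tested on simulated data with 200 planted losses and as many gains per comparison, and 100% of each were recovered in all 6. Planted regions were held by every library of 1 group and by none of the other, so recovery was set by construction. It checks the code and not the power to find partial changes. All libraries of a comparison were drawn alike from 1 reference list, so differences in list length were not simulated. Other simulated regions called lost and gained by chance numbered 442 and 434 for H3K4me1, 405 and 417 for PU.1, 670 and 683 for ATAC in Utx KO, 617 and 664 for Smarca4 gRNA in WT, 476 and 483 for Smarca4 gRNA in KO and 1083 and 1054 for Chd4 gRNA. Fisher's exact test at 0.05 called 5.0% of 200 simulated lists without an excess and 100% with an excess of 3 times. These lists were drawn region by region, without the clustering of real regions by gene. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.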

Results

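Chromatin was profiled in mouse haematopoietic stem and progenitor cells, the lineage-negative fraction of bone marrow, with and without Utx, a histone demethylase encoded by the X-linked gene Kdm6a. H3K4me1, a histone mark found at enhancers, was mapped in 2 wild-type (WT) and 2 Utx knockout (KO) libraries, and PU.1, an ETS family transcription factor encoded by Spi1, in 3 of each. Open chromatin was mapped by ATAC-seq in cultured cells that carried an empty guide RNA vector or a guide RNA (gRNA) against Smarca4, which encodes the remodelling enzyme Brg1, with 2 libraries for each guide in each Utx genotype. A separate ATAC set compared a gRNA against Chd4, which encodes a remodelling enzyme of the NuRD complex, with empty vector in Utx WT cells, again with 2 libraries each. The 2 input libraries had no peak list and entered no comparison.

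The peak lists held 43706 to 54654 H3K4me1 islands per library, 137850 to 171535 PU.1 islands and 24833 to 50927 ATAC peaks. Islands carried 6.93 to 14.2 M reads per H3K4me1 library and 20.4 to 27.8 M per PU.1 library, which is the part of each library that fell in islands and not its depth. The ATAC lists carry no count, so their depth is unknown. On average, libraries of a group shared more of their covered bases than libraries of different groups. The mean Jaccard index within and between groups was 0.621 and 0.543 for H3K4me1, 0.658 and 0.609 for PU.1, 0.746 and 0.665 for the Smarca4 ATAC set, and 0.651 and 0.547 for the Chd4 set. Every within-group pair lay above every between-group pair for H3K4me1, but not for the other assays. Chd4 gRNA replicate 1 was closer to the empty-vector libraries (0.603 and 0.659) than to gRNA replicate 2 (0.595). In Utx KO cells Smarca4 gRNA replicate 1 was closer to the empty-vector libraries (0.757 and 0.754) than to gRNA replicate 2 (0.713). The between-group mean of the Smarca4 set also pools pairs of different genotypes.

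The targeted genes were looked at first. Regions assigned to Kdm6a (chromosome X, 18160862 to 18279936, GRCm38) were held in Utx KO as well as in WT libraries. For H3K4me1 the WT libraries held 3 and 4 of 4 regions and the KO libraries 1 and 2, and 2 regions were lost. For PU.1 they held 7, 7 and 6 and 8, 9 and 8 of 9 regions, and for ATAC 3 and 4 and 5 and 5 of 5, with 1 region gained in each assay. At Smarca4 (chromosome 9, 21616106 to 21704230) both ATAC regions stayed after Smarca4 gRNA in Utx WT cells, and 1 of 2 was lost in Utx KO cells. At Chd4 (chromosome 6, 125095980 to 125130591) 0 of 5 regions were lost after Chd4 gRNA. Peak lists do not show whether a gene was deleted or edited, so these values check no label. Smarca4 lost 1 of 4 H3K4me1 regions and gained 1 of 11 PU.1 regions in Utx KO. Gata2 lost 1 of 5 H3K4me1 regions in Utx KO, 1 of 12 PU.1 regions in Utx KO and 1 of 10 ATAC regions after Chd4 gRNA. Gata1 gained 1 of 4 PU.1 regions in Utx KO and lost 1 of 3 ATAC regions after Smarca4 gRNA in Utx WT cells. At Spi1 no region was lost or gained, and 0 H3K4me1 islands were nearest to it. These 6 genes had no other lost or gained region in any comparison.

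**Figure D1:**
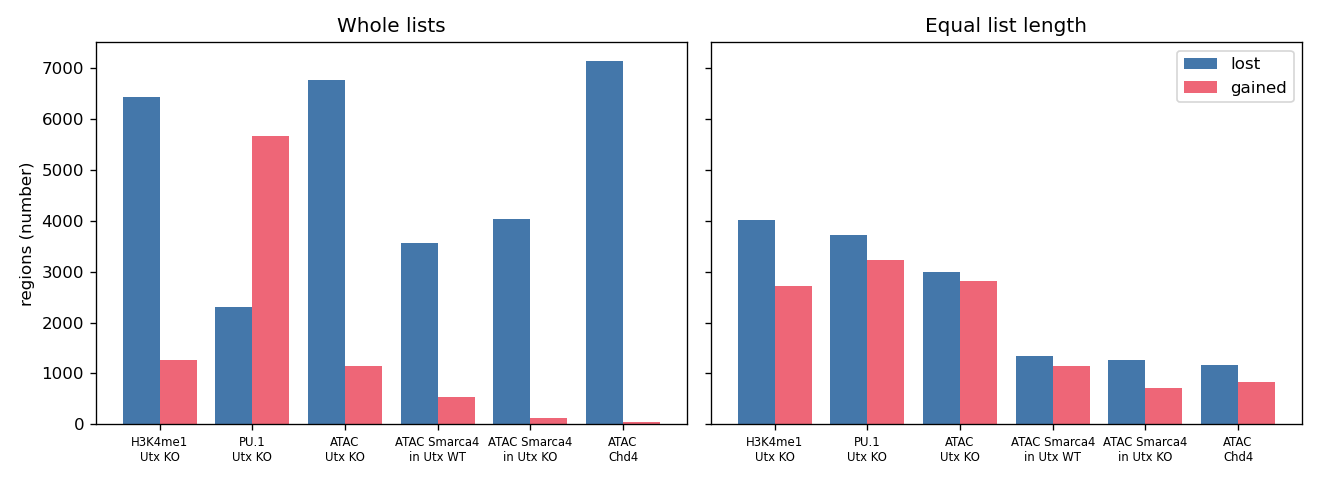
Number of lost and gained regions in each of the 6 comparisons, with whole peak lists on the left and lists trimmed to equal length on the right. Bars are counts by rule and carry no error bar. The PU.1 counts are 2295 lost and 5666 gained with whole lists.

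The H3K4me1 comparison asks which enhancer-marked regions depend on Utx. A lost region had a peak in every WT library and in no KO library, a gained region the reverse, and a kept region a peak in every library. Haematopoietic stem cell genes lost H3K4me1 regions in Utx KO more often than other genes, with 28 of 85 regions (32.9% against 17.1%) lost at 11 of 20 genes. Among them were Mllt3 with 6 of 23 regions, Meis1 with 5 of 22 and Prdm16 with 4 of 16, all transcriptional regulators known from stem cells. B cell genes gained H3K4me1 regions, 13 of 47 (27.7% against 3.94%), at 7 of 17 genes. These included the B lineage transcription factor Ebf1 with 4 of 16 regions, the B cell coactivator Pou2af1 with 3 of 5, the signalling adaptor Bank1 with 2 of 16 and the kinase gene Blk with 1 of 3. Of B cell regions, 2 of 31 were lost, both at Bank1. The denominator of a list is its regions held by every library of the group with the peak, and that of a single gene is all regions nearest to it. By Fisher's exact test across regions, two-sided and adjusted over 156 tests, the odds ratio was 2.38 (1.46 to 3.81, 95% interval, adjusted p = 0.0321) for the stem cell list and 9.32 (4.50 to 18.2, adjusted p = 3.62e-06) for the B cell list. Regions are not independent replicates, so these tests describe these libraries. In Fisher's exact test the stem cell result missed the threshold without KO replicate 1 (odds ratio 2.26, adjusted p = 0.0575), without Mllt3 (2.22, 0.117), with regions within 50 kb of a gene (2.18, 0.166) and at equal list length (2.31, 0.195), with an odds ratio near that of whole lists each time. The B cell result passed without each library in turn, with odds ratios from 3.67 without KO replicate 2 to 7.73 without KO replicate 1.

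Only the stem cell and B cell lists passed among 13 gene lists, each in the direction given. Losses lay at 13 of 21 erythroid genes (Ank1 2 of 7 regions and Bcl11a 2 of 22) and 11 of 21 megakaryocyte genes (Rab27b 5 of 8 regions and Thbs1 4 of 24). Losses also reached 5 of 15 mast cell and basophil genes (Kit 7 of 26 regions and Gzmb 2 of 5) and 1 of 21 granulocyte genes (Csf3r 1 of 3 regions). Losses lay at 6 of 24 monocyte and macrophage genes (Ly86 3 of 24 regions and F13a1 2 of 14) and 6 of 16 T and NK cell genes (Cd247 1 of 4 regions and Cd28 1 of 16). Losses touched 6 of 15 stroma and endothelium genes (Pdgfra 3 of 12 regions and Col1a2 2 of 3) and 7 of 16 ETS family factor genes (Ets1 2 of 20 regions and Etv6 2 of 5). Losses lay at 3 of 11 GATA partner factor genes (Runx1 2 of 30 regions and Cbfa2t3 1 of 5) and 9 of 25 growth and tumour suppression genes (Myc 9 of 36 regions). Losses also reached 4 of 16 housekeeping genes (Ywhaz 2 of 16 regions and Eef1a1 1 of 3). Gains lay at 0 of 21 erythroid genes and 2 of 21 megakaryocyte genes (Angpt1 1 of 20 regions). Gains also reached 2 of 15 mast cell and basophil genes (Fcer1a 1 of 2 regions) and 2 of 21 granulocyte genes (Csf3r 1 of 3 regions). Gains lay at 1 of 24 monocyte and macrophage genes (Csf2ra 1 of 6 regions) and 1 of 20 haematopoietic stem cell genes (Meis1 3 of 22 regions). Gains touched 2 of 16 T and NK cell genes (Bcl11b 1 of 3 regions) and 2 of 15 stroma and endothelium genes (Kdr 1 of 16 regions). Gains lay at 3 of 16 ETS family factor genes (Ets2 3 of 11 regions) and 1 of 11 GATA partner factor genes (Cbfa2t3 1 of 5 regions). Gains also reached 2 of 25 growth and tumour suppression genes and 1 of 16 housekeeping genes (Hprt 1 of 3 regions). Closest to the threshold was the loss at erythroid genes (18 of 55 regions, 32.7% against 17.1% elsewhere, odds ratio 2.36, Fisher's exact adjusted p = 0.117), which passed without KO replicate 2 (adjusted p = 0.00145). Of the 26 tests, 5 had an unadjusted p under 0.05.

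Single genes with most lost H3K4me1 regions were Rybp, a Polycomb complex gene, with 12 of 37 (chromosome 6, 100228565 to 100287358), Dennd1a with 12 of 28 (chromosome 2, 37798990 to 38287410), St6galnac3 with 10 of 25, the transcription factor gene Nfia with 10 of 44 and Arhgef28 with 9 of 31. None of these had a gained region. Genes with many gains included Hs6st3 with 6 of 14 (chromosome 14, 119137516 to 119869815), Cdca7 with 5 of 15, the endothelin receptor gene Ednra with 4 of 9 and Edil3 with 4 of 11. The lost islands that ranked highest in WT replicate 1 lay on chromosome 18 61944001 to 61961799 (within Sh3tc2), chromosome 6 55248201 to 55266199 (within Mindy4) and chromosome 6 39420601 to 39437799 (within Mkrn1). Those gained and ranked highest in KO replicate 1 lay on chromosome 8 77709601 to 77729599 (within Ednra), chromosome 9 124256201 to 124259399 (8484 bp from Gm39469) and chromosome 14 51863801 to 51873199 (9157 bp from Ear6).

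In all, 6419 of 58677 regions were lost, 1262 gained and 26944 kept (log2 ratio of lost to gained 2.35, and 0.41 to 2.15 with SD 0.92 in the 4 pairs of single libraries). Lost and gained islands were narrow and rarely at gene ends: medians were 3199 and 3399 bp against 6599 bp for kept regions, and 10.5% and 12.7% lay within 1 kb of a gene end against 48.3%. Both differences arise partly by construction, since kept regions merge peaks of both groups. The number of islands fell from 53024 ± 2305 to 43898 ± 271 (mean and SD, n = 2 each), with p = 0.333 by exact permutation, the smallest that 2 against 2 allows. The groups differed in 7681 lost and gained regions in all, against at most 2110 for any other of the 3 splits of these libraries. Lists trimmed to the shortest gave 4013 lost and 2712 gained, log2 ratio 0.57. Leaving out a library eased the rule: 13395 regions were lost without WT replicate 1, and 4438, 2769 and 3407 were gained without WT replicate 2, KO replicate 1 and KO replicate 2.

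For PU.1, which binds ETS motifs and drives myeloid and B cell differentiation, the question is where binding changes without Utx. Most gained regions lay nearest to Adamtsl1 with 16 of 64 (chromosome 4, 85513852 to 86428390), the X-linked formin gene Diaph2 with 16 of 140 (chromosome X, 129749668 to 130465834), Zfpm2, which encodes a GATA cofactor, with 13 of 50, the transcriptional repressor gene Zeb2 with 13 of 239 and Dip2c with 13 of 60. Most lost regions lay nearest to Arhgap26 with 7 of 105 (chromosome 18, 38601617 to 39376285), Sdk2 with 7 of 47 (chromosome 11, 113776374 to 114067029), Zeb2 again with 6 of 239, Arpp21 with 6 of 54 and Fat1 with 5 of 39. The strongest lost islands in WT replicate 1 lay on chromosome 2 51207001 to 51207599 (57889 bp from Rnd3), chromosome 14 60703401 to 60705399 (within Spata13) and chromosome 17 49899801 to 49900799 (within Kif6). The strongest gained islands in KO replicate 1 lay on chromosome 2 65411801 to 65412799 (44318 bp from Scn3a), chromosome 2 52638201 to 52639399 (within Cacnb4) and chromosome 2 47535401 to 47536399 (1277709 bp from Acvr2a).

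No gene list passed Fisher's exact test for PU.1, and 4 of 26 tests had an unadjusted p under 0.05. Among them, none of 356 monocyte and macrophage regions was lost (2.06% elsewhere, exact adjusted p = 0.0575), and 6 of 355 were gained (1.69% against 4.79%, exact adjusted p = 0.117). Erythroid genes held 1 gained region of 170 (exact adjusted p = 0.117) and B cell genes 12 of 121 (9.92% against 4.77%, exact adjusted p = 0.226). Some of these passed Fisher's exact test when a library was left out: the scarcity of gains at erythroid and at monocyte and macrophage genes without WT replicate 1 (adjusted p = 0.0131 and 0.0102), the scarcity of losses and gains at monocyte and macrophage genes without WT replicate 2 (0.0348 and 0.0429), and that of gains at erythroid genes without KO replicate 1 (0.0424). Gains lay at 6 of 16 B cell genes (Bank1 4 of 60 regions and Ebf1 4 of 47) and 6 of 22 haematopoietic stem cell genes (Meis1 3 of 99 regions). Gains also reached 3 of 20 T and NK cell genes (Eomes 2 of 12 regions and Gata3 2 of 80) and 1 of 20 erythroid genes (Ank1 1 of 21 regions). Gains lay at 2 of 21 megakaryocyte genes (Angpt1 5 of 80 regions and Thbs1 2 of 73) and 1 of 16 mast cell and basophil genes (Kit 2 of 66 regions). Gains touched 3 of 24 granulocyte genes (Fcnb 2 of 17 regions and Ltf 1 of 12) and 4 of 25 monocyte and macrophage genes (Ly86 2 of 89 regions and Tlr4 2 of 63). Gains lay at 7 of 17 ETS family factor genes (Ets1 6 of 84 regions and Elf2 1 of 22) and 3 of 13 GATA partner factor genes (Gata1 1 of 4 regions and Runx1 1 of 139). Gains also reached 9 of 26 growth and tumour suppression genes (Myc 7 of 169 regions and Cdkn2c 2 of 14) and 5 of 20 housekeeping genes (B2m 1 of 3 regions and Gapdh 1 of 3). Gains lay at 6 of 16 stroma and endothelium genes (Vcam1 2 of 19 regions and Col1a2 1 of 18). Losses lay at 1 of 16 B cell genes (Blnk 1 of 15 regions) and 5 of 22 haematopoietic stem cell genes (Prdm16 4 of 23 regions). Losses also reached 5 of 20 T and NK cell genes (Cd247 1 of 15 regions) and 2 of 20 erythroid genes (Bcl11a 1 of 138 regions). Losses lay at 5 of 21 megakaryocyte genes (Cd9 1 of 27 regions) and 4 of 16 mast cell and basophil genes (Kit 2 of 66 regions). Losses touched 2 of 24 granulocyte genes (Cd177 1 of 9 regions) and 2 of 17 ETS family factor genes (Elk3 1 of 33 regions). Losses lay at 4 of 13 GATA partner factor genes (Runx1 2 of 139 regions) and 7 of 26 growth and tumour suppression genes (Myc 2 of 169 regions). Losses also reached 1 of 20 housekeeping genes and 5 of 16 stroma and endothelium genes (Runx2 3 of 71 regions).

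For PU.1, 2295 of 197241 regions were lost, 5666 gained and 98601 kept (log2 ratio of lost to gained -1.30, and -1.86 to 0.41 with SD 0.88 in the 9 pairs of single libraries). Lost and gained regions were narrow and rarely at gene ends: medians were 599 and 599 bp against 1199 bp for kept regions, and 5.41% and 4.38% lay within 1 kb of a gene end against 13.6%. The excess of gains was not shared by KO replicate 2, whose list was the shortest of its group: 3 of 9 library pairs, all with that replicate, had more lost than gained, and without it 12057 regions were gained (log2 ratio -2.22). When a library had to cover 50% of a region, 4380 were lost and the excess of gains was gone (log2 ratio -0.0151). Trimmed to the shortest list, the libraries gave 3716 lost and 3221 gained, log2 ratio 0.21, a reversed sign. There were 7961 lost and gained regions in all, against at most 1514 for any other of the 10 splits of these libraries. Island numbers were 141554 ± 3215 in WT and 157171 ± 17019.8 (mean and SD, n = 3 each) in KO, with p = 0.30 by exact permutation (smallest possible 0.1). Without WT replicate 1, WT replicate 3 or KO replicate 1, 3530, 3809 and 4795 regions were lost.

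In cultured cells with empty vector, the ATAC comparison asks which open regions depend on Utx. Cmip lost 15 of 45 (chromosome 8, 117257019 to 117461506) regions, Nav1 13 of 28 (chromosome 1, 135434580 to 135688350), the transcription factor gene Zfhx3 11 of 39, the phosphodiesterase gene Pde4d 10 of 66 and Gramd1b 10 of 32, with no gain at any of them. Gains were few per gene: Zeb2 gained 5 of 47 regions, Auts2 5 of 28 (chromosome 5, 131437333 to 132543220), the predicted gene Gm11677 5 of 14, Tmtc2 5 of 29 and Ccn3 all 4 of 4 (chromosome 15, 54745910 to 54753762). The widest lost regions in WT replicate 1 lay on chromosome 2 148043476 to 148045225 (within Foxa2), chromosome 4 134371035 to 134372733 (within Extl1) and chromosome 2 118302081 to 118303785 (within Gpr176). The widest gained regions in KO replicate 1 lay on chromosome 16 97462992 to 97465232 (5732 bp from Fam3b), chromosome 15 54745074 to 54746525 (within Ccn3) and chromosome 3 102203769 to 102205040 (within Vangl1).

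No list passed Fisher's exact test in this comparison, and 1 of 26 tests had an unadjusted p under 0.05. That test was the gain at mast cell and basophil genes (10 of 125 regions, 8.0% against 3.16% elsewhere, odds ratio 2.66, Fisher's exact adjusted p = 0.117), with the mast cell protease gene Cpa3 at 4 of 16 regions and the receptor gene Il1rl1 at 2 of 22. Losses lay at 9 of 17 mast cell and basophil genes (Hdc 2 of 6 regions and Kit 2 of 37) and 9 of 16 megakaryocyte genes (Itgb3 4 of 10 regions and Rab27b 3 of 18). Losses also reached 5 of 16 erythroid genes (Blvrb 3 of 4 regions and Bcl11a 2 of 25) and 6 of 17 granulocyte genes (Cebpa 1 of 2 regions and Cebpe 1 of 4). Losses lay at 10 of 17 ETS family factor genes (Etv6 4 of 38 regions and Fli1 4 of 34) and 5 of 13 GATA partner factor genes (Runx1 7 of 59 regions and Cbfa2t3 4 of 19). Losses touched 15 of 26 growth and tumour suppression genes (Bcl2 5 of 19 regions and Dusp6 4 of 22) and 8 of 21 haematopoietic stem cell genes (Mecom 4 of 26 regions and Meis1 2 of 44). Losses lay at 9 of 22 monocyte and macrophage genes (Ly86 2 of 21 regions) and 3 of 12 B cell genes (Blnk 3 of 4 regions and Bank1 1 of 8). Losses also reached 4 of 16 T and NK cell genes (Gata3 4 of 23 regions and Cd3e 1 of 1) and 6 of 14 stroma and endothelium genes (Pecam1 4 of 11 regions and Cxcl12 3 of 9). Losses lay at 4 of 20 housekeeping genes (Actb 2 of 8 regions and Gusb 1 of 4). Gains lay at 5 of 21 haematopoietic stem cell genes (Cd34 1 of 17 regions) and 6 of 17 mast cell and basophil genes (Cpa3 4 of 16 regions). Gains also reached 2 of 16 T and NK cell genes (Gata3 2 of 23 regions) and 2 of 16 megakaryocyte genes (Cd9 1 of 13 regions). Gains lay at 2 of 22 monocyte and macrophage genes (Klf4 1 of 8 regions) and 2 of 14 stroma and endothelium genes (Emcn 1 of 3 regions). Gains touched 2 of 26 growth and tumour suppression genes (Myc 1 of 33 regions) and 1 of 12 B cell genes (Bank1 1 of 8 regions). Gains lay at 1 of 16 erythroid genes (Bcl11a 1 of 25 regions) and 1 of 17 granulocyte genes (Retnlg 1 of 1 region). Gains also reached 1 of 17 ETS family factor genes (Erf 1 of 3 regions) and 0 of 13 GATA partner factor genes. Gains lay at 0 of 20 housekeeping genes.

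Of the ATAC regions, 6755 of 59456 were lost, 1141 gained and 33039 kept (log2 ratio of lost to gained 2.57, and 1.78 to 2.16 with SD 0.19 in the 4 pairs of single libraries). Median widths of lost and gained ATAC regions were 380 and 334 bp against 736 bp for kept regions, and 8.65% and 10.2% lay within 1 kb of a gene end against 33.8%. Peak numbers fell from 50886 ± 58.0 to 40750.5 ± 387 (mean and SD, n = 2 each), with p = 0.333 by exact permutation, the smallest that 2 against 2 allows. There were 7896 lost and gained regions in all, against at most 865 for any other of the 3 splits of these libraries. Trimming to the shortest list gave 2985 lost and 2805 gained, log2 ratio 0.09. Leaving out WT replicate 1 or 2 gave 11559 and 11062 lost regions. Gained regions numbered 2097, 2367 and 2302 without WT replicate 2, KO replicate 1 and KO replicate 2.

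Guide RNA against Smarca4 in Utx WT cells tests which open regions need Brg1. Gse1 lost 8 of 49 (chromosome 8, 120228501 to 120581383) regions, the haematopoietic transcription factor gene Runx1 6 of 58 (chromosome 16, 92601466 to 92826074), Zswim6 6 of 22, Trib2 6 of 27 and the X-linked corepressor gene Bcor 6 of 36. Gained regions were fewer in all than the 664 called by chance in simulated unchanged lists. Those lists were all drawn alike from empty-vector replicate 1, whereas the real gRNA lists were shorter, which lowers gains. At equal list length 1145 regions were gained. The simulation thus cannot tell whether the gains named next exceed chance calls. Genes with many gains included Osbpl8 with 5 of 46 (chromosome 10, 111164742 to 111297249), Csf2rb with 3 of 19 (chromosome 15, 78325800 to 78351001), its neighbour Csf2rb2 with 2 of 18 and Tmeff2 with 2 of 12. Csf2rb encodes a cytokine receptor chain of myeloid cells. In empty-vector replicate 1 the widest lost regions lay on chromosome 4 141871623 to 141872691 (within Efhd2), chromosome 6 87778019 to 87779010 (within Gp9) and chromosome 4 129959657 to 129960481 (2541 bp from Spocd1). In gRNA replicate 1 the widest gained regions lay on chromosome 13 83732348 to 83733299 (65268 bp from Mef2c), chromosome 15 78352812 to 78353688 (1810 bp from Csf2rb) and chromosome 2 148754700 to 148755744 (within Cstl1).

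None of the lists passed Fisher's exact test, and 1 of 26 tests had an unadjusted p under 0.05, the loss at erythroid genes (9 of 50 regions, 18.0% against 8.19% elsewhere, odds ratio 2.46, Fisher's exact adjusted p = 0.250). Losses lay at 6 of 16 erythroid genes (Bcl11a 4 of 26 regions and Blvrb 1 of 4) and 6 of 13 GATA partner factor genes (Runx1 6 of 58 regions and Cbfa2t3 2 of 16). Losses also reached 5 of 16 mast cell and basophil genes (Kit 4 of 36 regions and Hdc 2 of 6) and 5 of 21 haematopoietic stem cell genes (Meis1 3 of 39 regions and Mecom 2 of 26). Losses lay at 5 of 17 ETS family factor genes (Erg 2 of 23 regions and Ets1 2 of 20) and 10 of 26 growth and tumour suppression genes (Bcl2 3 of 22 regions). Losses touched 5 of 22 monocyte and macrophage genes (Ccr2 2 of 5 regions and Ly86 2 of 22) and 6 of 16 T and NK cell genes (Cd247 1 of 4 regions and Cd3e 1 of 1). Losses lay at 5 of 14 stroma and endothelium genes (Cxcl12 2 of 9 regions and Pdgfra 2 of 16) and 1 of 13 B cell genes (Igll1 1 of 2 regions). Losses also reached 2 of 15 granulocyte genes (Csf3r 1 of 1 region and Ltf 1 of 3) and 3 of 18 megakaryocyte genes (Gp9 1 of 2 regions and Itgb3 1 of 10). Losses lay at 3 of 20 housekeeping genes (Actb 1 of 8 regions and Gusb 1 of 4). Gains lay at 3 of 16 mast cell and basophil genes (Gzmb 1 of 6 regions) and 3 of 26 growth and tumour suppression genes (Lmo1 2 of 7 regions). Gains also reached 2 of 17 ETS family factor genes (Elk3 1 of 9 regions) and 2 of 18 megakaryocyte genes (Rab27b 1 of 18 regions). Gains lay at 1 of 13 B cell genes (Ebf1 1 of 9 regions) and 1 of 14 stroma and endothelium genes (Emcn 1 of 3 regions). Gains touched 1 of 20 housekeeping genes. No gene of the erythroid, granulocyte, monocyte and macrophage, stem cell, GATA partner or T and NK cell lists had a gain. Without gRNA replicate 2, the gain at mast cell and basophil genes passed Fisher's exact test (adjusted p = 0.0296).

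In all, 3562 of 59756 regions were lost, 530 gained and 35366 kept (log2 ratio of lost to gained 2.75, and 0.77 to 2.18 with SD 0.64 in the 4 pairs of single libraries). Lost and gained regions had median widths of 329 and 370 bp against 741 bp for kept regions, and 9.71% and 11.7% lay within 1 kb of a gene end against 31.9%. Peak numbers fell from 50886 ± 58.0 to 44103 ± 2953 (mean and SD, n = 2 each), p = 0.333 by exact permutation, the smallest possible. There were 4092 lost and gained regions in all, against at most 1698 for any other of the 3 splits of these libraries, and 1341 lost and 1145 gained at equal list length, log2 ratio 0.23. Without empty-vector replicate 1 or 2 and without gRNA replicate 2, 7371, 7355 and 6759 regions were lost. Gained regions numbered 1021, 1541, 3008 and 1721 without empty-vector replicate 1, empty-vector replicate 2, gRNA replicate 1 and gRNA replicate 2.

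The same guide in Utx KO cells asks what Brg1 maintains in the absence of Utx. The genes with most losses were Auts2 with 9 of 26 (chromosome 5, 131437333 to 132543220), Tmtc2 with 8 of 26 (chromosome 10, 105187663 to 105574479), Hs6st1 with 7 of 29, Nos1ap with 6 of 16 and Fhit with 6 of 27. Gained regions were fewer in all than the 483 called by chance in simulated lists without a change. As in WT cells, those lists were not shortened like the real gRNA lists, and 715 regions were gained at equal list length. Whether the gains named below exceed chance calls thus cannot be told. Gains were seen at Trpm8 with 2 of 11 (chromosome 1, 88306735 to 88388853), Mgat1 with 2 of 5 (chromosome 11, 49244191 to 49263027), Cntn4 with 2 of 6, the neurotrophin gene Bdnf with 1 of 2 and Fmn2 with 1 of 10. The widest regions lost from empty-vector replicate 1 lay on chromosome 6 114690728 to 114691844 (within Atg7), chromosome X 105764070 to 105765007 (within Fgf16) and chromosome X 10151920 to 10152860 (5355 bp from Rpgr). The widest gained in gRNA replicate 1 lay on chromosome 2 109693418 to 109694382 (within Bdnf), chromosome 1 174502180 to 174503082 (within Fmn2) and chromosome 17 85679679 to 85680383 (within Six2).

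Here too no list passed Fisher's exact test, and 1 of 26 had an unadjusted p under 0.05, the loss at erythroid genes (10 of 37 regions, 27.0% against 11.2% elsewhere, odds ratio 2.95, Fisher's exact adjusted p = 0.117). Losses lay at 6 of 14 erythroid genes (Bcl11a 3 of 18 regions and Car2 2 of 4) and 8 of 17 mast cell and basophil genes (Mitf 3 of 31 regions and Cpa3 2 of 17). Losses also reached 5 of 14 megakaryocyte genes (Cd9 3 of 12 regions and Angpt1 2 of 16) and 7 of 21 monocyte and macrophage genes (Ccr2 2 of 4 regions and F13a1 2 of 2). Losses lay at 6 of 20 haematopoietic stem cell genes (Mecom 4 of 19 regions and Meis1 2 of 40) and 5 of 17 ETS family factor genes (Elk3 3 of 9 regions and Ets1 2 of 16). Losses touched 2 of 13 GATA partner factor genes (Runx1 3 of 47 regions and Gfi1b 1 of 5) and 13 of 26 growth and tumour suppression genes (Cdk6 4 of 18 regions and Cdkn2b 4 of 13). Losses lay at 3 of 12 B cell genes (Bank1 2 of 6 regions) and 4 of 15 T and NK cell genes (Gata3 2 of 18 regions and Klrb1c 1 of 3). Losses also reached 6 of 14 stroma and endothelium genes (Pdgfra 3 of 17 regions and Pecam1 2 of 8) and 1 of 15 granulocyte genes (S100a8 1 of 1 region). Losses lay at 2 of 20 housekeeping genes (Ywhaz 4 of 20 regions and Sdha 1 of 1). Gains lay at 1 of 17 mast cell and basophil genes (Kit 1 of 34 regions) and 1 of 26 growth and tumour suppression genes (Mcl1 1 of 8 regions). Gains also reached 1 of 14 stroma and endothelium genes (Pdgfra 1 of 17 regions) and 1 of 20 housekeeping genes. No gene of the other 9 lists had a gain. In Fisher's exact test the erythroid loss passed without gRNA replicate 1 and a mast cell and basophil gain without gRNA replicate 2 (adjusted p = 0.0453 and 0.00955).

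In all, 4022 of 47537 regions were lost, 135 gained and 26176 kept (log2 ratio of lost to gained 4.90, and 1.40 to 2.66 with SD 0.68 in the 4 pairs of single libraries). Median widths were 324 and 378 bp and 755 bp for lost, gained and kept regions in that order, and 6.66% and 25.2% lay within 1 kb of a gene end against 40.5%. Peak numbers were 40750.5 ± 387 with empty vector and 32952 ± 4274 (mean and SD, n = 2 each) with gRNA, p = 0.333 by exact permutation, the smallest possible. There were 4157 lost and gained regions in all, against at most 1077 for any other of the 3 splits of these libraries, and 1268 lost and 715 gained at equal list length, log2 ratio 0.83. Without empty-vector replicate 1, empty-vector replicate 2 and gRNA replicate 1, 7084, 6681 and 9459 regions were lost. Gained regions numbered 315, 344, 1827 and 1664 without empty-vector replicate 1, empty-vector replicate 2, gRNA replicate 1 and gRNA replicate 2.

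Whether Brg1 editing acted differently in the 2 genotypes was tested directly. Within same-numbered pairs of empty and gRNA libraries, the log2 ratio of peaks found only with empty vector to peaks found only with gRNA was 1.45 ± 0.47 in Utx WT and 2.03 ± 0.89 in Utx KO cells (mean and SD, n = 2 each). The difference of 0.58 had p = 0.667 by a two-sided exact permutation test, whose smallest possible p is 0.333. No gene list differed between genotypes at 0.05 after adjustment, by a Woolf test of the odds ratios across regions. GATA partner genes came closest, with an odds ratio for loss of 1.65 in WT and 0.461 in KO cells.

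Regions that opened without Utx had often closed after Smarca4 gRNA. Of 1133 regions gained in Utx KO cells, 598 (52.8%) were lost after Smarca4 gRNA in those cells, against 8.27% of 32815 regions held by all empty-vector libraries. Of 6683 regions lost in Utx KO cells, 2146 (32.1%) were also lost after Smarca4 gRNA in Utx WT cells, against 2.38% of the same kept regions. By Fisher's exact test the odds ratios were 12.4 (10.9 to 14.1) and 19.4 (17.8 to 21.2). Both comparisons of each pair share control libraries, and unchanged groups simulated against those controls gave median odds ratios of 5.56 (range 4.22 to 7.11) and 6.77 (5.68 to 8.17) in 100 draws. Over strata of width the odds ratios were 4.15 and 5.75. The same unchanged groups gave medians of 1.51 (1.14 to 1.95) and 1.46 (1.23 to 1.84) over these strata, a test chosen after seeing the data. The simulation draws regions by width alone. Independent lists would share 547 losses between Utx KO and Smarca4 gRNA in WT cells, and 2146 were shared. With the empty-vector libraries split 1 and 1, so that none served both comparisons, the odds ratios over strata of width were 1.28 and 1.25 for regions gained in Utx KO (at most 0.847 and 0.854 in unchanged groups) and 2.71 and 2.66 for regions lost in Utx KO (at most 0.849 and 0.884 in unchanged groups), a test chosen after seeing the data. A region must then be held by the other control to count as lost, which lowers these values by construction. An excess over width remained, but each split counted as lost the same 598 and 2146 regions as the shared controls did. Only the regions set beside them changed, so the splits are no separate evidence. However, the unchanged groups were drawn at the call rate of the empty-vector libraries, whereas the gRNA lists were shorter. In the simulation with shared controls they lost 1.56% and 1.11% of kept regions, against 8.27% and 2.38% observed. The excess over unchanged groups therefore cannot be told from an effect of shorter gRNA lists, and peak strength beyond width was not tested.

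The Chd4 set asks which open regions of Utx WT cells need this remodeller. Nedd9, an adhesion scaffold gene, lost 13 of 30 (chromosome 13, 41309916 to 41487362) regions, the phosphatase gene Ptpre 12 of 36 (chromosome 7, 135537824 to 135686294), the erythroid transcription factor gene Sox6 11 of 16 (chromosome 7, 115470872 to 116040776) with none kept, St3gal1 10 of 35 and the ETS factor gene Etv6 9 of 42. Gained regions were fewer in all than the 1054 called by chance in simulated unchanged libraries. Those libraries were not shortened like the real gRNA lists, and 834 regions were gained at equal list length. The simulation thus cannot tell whether the gains exceed chance calls. The gained regions were scattered, with 2 of 5 at Ugt1a1, 1 of 2 at Wdr63, 1 of 19 at Nav1, 1 of 1 at Ccdc89 and 1 of 3 at Gcsam. The widest lost regions of empty-vector replicate 1 lay on chromosome 13 51792367 to 51793917 (within Sema4d), chromosome 4 136172145 to 136173674 (within E2f2) and chromosome 10 62885883 to 62887403 (within Tet1). The widest gained regions of gRNA replicate 1 lay on chromosome 3 146107414 to 146108259 (within Wdr63), chromosome 1 135633465 to 135634150 (within Nav1) and chromosome 7 90426271 to 90426769 (within Ccdc89).

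Chd4 gRNA left no list past Fisher's exact test, and 2 of 26 tests had an unadjusted p under 0.05. These were the losses at erythroid genes (15 of 37 regions, 40.5% against 18.8% elsewhere, odds ratio 2.95, Fisher's exact adjusted p = 0.0866) and at GATA partner genes (9 of 89 regions, 10.1% against 18.8% elsewhere, odds ratio 0.485, Fisher's exact adjusted p = 0.449). Losses lay at 6 of 14 erythroid genes (Bcl11a 8 of 23 regions and Cd36 2 of 6) and 11 of 16 megakaryocyte genes (Thbs1 6 of 26 regions and Cd9 3 of 15). Losses also reached 11 of 16 mast cell and basophil genes (Cd200r3 2 of 23 regions and Kit 2 of 17) and 14 of 24 granulocyte genes (Itgam 4 of 9 regions and Cd177 2 of 4). Losses lay at 14 of 24 monocyte and macrophage genes (Ly86 7 of 22 regions and F13a1 3 of 12) and 10 of 20 haematopoietic stem cell genes (Cd34 3 of 13 regions and Meis1 3 of 23). Losses touched 11 of 17 ETS family factor genes (Etv6 9 of 42 regions and Ets1 7 of 29) and 6 of 13 GATA partner factor genes (Lmo2 3 of 10 regions and Zfpm1 2 of 9). Losses lay at 21 of 26 growth and tumour suppression genes (Dusp6 6 of 28 regions and Ccnd2 5 of 15) and 2 of 9 B cell genes (Il7r 2 of 5 regions and Blnk 1 of 3). Losses also reached 5 of 12 T and NK cell genes (Cd28 3 of 5 regions) and 8 of 16 stroma and endothelium genes (Acta2 3 of 6 regions and Pecam1 2 of 10). Losses lay at 3 of 19 housekeeping genes (Ywhaz 2 of 19 regions and Gapdh 1 of 2). Among list genes only Etv6 had a gained region, 1 of 42.

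In all, 7140 of 52201 regions were lost, 49 gained and 22275 kept (log2 ratio of lost to gained 7.19, and 1.89 to 6.18 with SD 1.84 in the 4 pairs of single libraries). Lost and gained regions measured 375 and 346 bp against 819 bp for kept regions, and 9.34% and 21.3% lay within 1 kb of a gene end against 40.6%. Peak numbers fell from 45084 ± 5096 to 29631 ± 6785 (mean and SD, n = 2 each), p = 0.333 by exact permutation, the smallest possible. There were 7189 lost and gained regions in all, against at most 1645 for any other of the 3 splits of these libraries, and 1171 lost and 834 gained at equal list length, log2 ratio 0.49. Without gRNA replicate 1 or empty-vector replicate 2, 14989 and 15554 regions were lost. Gained regions numbered 231, 102, 241 and 985 without empty-vector replicate 1, empty-vector replicate 2, gRNA replicate 1 and gRNA replicate 2.

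PU.1 and H3K4me1 were then joined to the ATAC regions, although culture is described for the ATAC cells only. PU.1 bound in all WT libraries at 54.0% of ATAC regions lost in Utx KO and 25.4% of those gained, against 71.3% of kept ones. With PU.1 peaks of the KO libraries the shares were 53.5%, 26.8% and 71.1%. H3K4me1 of the WT libraries marked 70.8% of lost, 28.4% of gained and 77.5% of kept regions, and that of the KO libraries 60.7%, 24.3% and 74.3%. The odds ratios against kept regions by Fisher's exact test were 0.473 and 0.467 for PU.1 of WT and KO at lost regions, 0.137 and 0.149 for PU.1 at gained regions, 0.702 and 0.533 for H3K4me1 at lost regions, and 0.115 and 0.111 for H3K4me1 at gained regions. Over strata of width, PU.1 at lost regions missed the threshold, with odds ratios of 0.947 and 0.955, and H3K4me1 at lost regions turned to an excess, 1.53 and 1.24. Gained regions kept their lower share, with 0.248 for PU.1 of WT and 0.20 for H3K4me1 of WT.

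Regions lost after Smarca4 or Chd4 gRNA were less often bound or marked than kept ones. In Utx WT cells PU.1 of WT lay at 44.5% of lost and 71.6% of kept regions after Smarca4 gRNA, and H3K4me1 of WT at 60.6% and 78.4% (Fisher's exact odds ratios 0.318 and 0.422; 0.609 and 0.904 over strata of width). In Utx KO cells PU.1 of KO lay at 40.9% against 75.9%, and H3K4me1 of KO at 43.5% against 79.3% (0.220 and 0.201; 0.455 and 0.451 over strata). Regions lost after Chd4 gRNA had PU.1 of WT at 68.2% against 89.7% and H3K4me1 of WT at 68.3% against 86.6% (0.245 and 0.334; 0.566 and 0.768 over strata). Among H3K4me1 islands, PU.1 of WT lay at 49.4% of lost, 50.9% of gained and 89.7% of kept islands, and PU.1 of KO at 44.3%, 70.8% and 90.4%. Kept islands were wider. Over strata of island reads, which rose with width, the odds ratios against kept islands were 0.175 at lost and 0.209 at gained islands for PU.1 of WT, and 0.129 and 0.473 for PU.1 of KO.

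The share of peaks on the X chromosome was among the values fixed for each library. For PU.1 it was 2.75% ± 0.0680 in Utx WT and 3.12% ± 0.0663 in Utx KO libraries (mean and SD, n = 3 each, p = 0.10 by exact permutation, the smallest possible). For ATAC with empty vector it was 2.23% ± 0.107 and 2.56% ± 0.0141 (n = 2 each, p = 0.333 by exact permutation, the smallest possible). In both, every KO library lay above every WT library. The H3K4me1 shares of 1.75% ± 0.390 and 1.98% ± 0.00550 overlapped. At equal list length, a setting chosen after seeing the data, they were 1.53% and 1.95%, and the lowest KO library lay 0.129 percentage points above the highest WT library. After Smarca4 gRNA the share moved by 0.044 percentage points in Utx WT and -0.052 in Utx KO cells, and after Chd4 gRNA by -0.023.

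**Figure D2:**
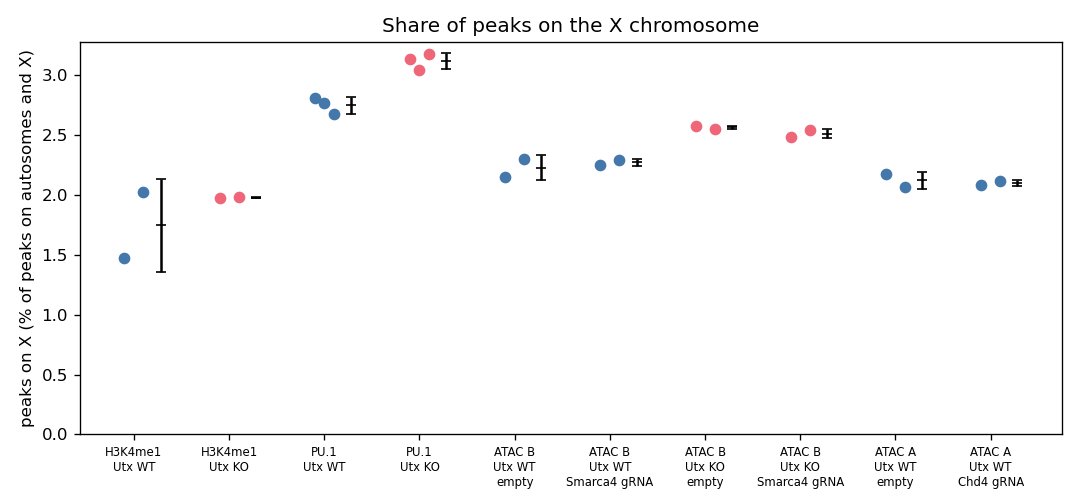
Share of peaks on the X chromosome, in percent of peaks on autosomes and X, for each library (points) with the mean and SD of each group (bars beside the points). Utx KO groups are red and WT groups blue; the PU.1 and ATAC empty-vector KO libraries lie above their WT libraries.

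Peaks at gene ends made up more of the shorter Utx KO lists. The share within 1 kb of a gene end was 30.5% ± 0.193 in WT and 35.2% ± 0.610 in KO libraries for H3K4me1, and 25.6% ± 0.324 and 29.7% ± 0.224 for ATAC (mean and SD, n = 2 each, each p = 0.333 by exact permutation). Covered length was 243 and 203 Mb for H3K4me1, 124 and 122 Mb for PU.1, and 32.4 and 25.7 Mb for ATAC with empty vector.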

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

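All settings were chosen before the data were examined except gene lists at equal list length, gene lists without each library or without Ebf1 or Mllt3, other splits and the X share at equal list length, and split controls for the joins of Utx and Smarca4, which were chosen after seeing the data. The direction of the log2 lost to gained ratio held under every setting but the equal list length for PU.1, and the B cell gain of H3K4me1 stayed past the threshold in every setting run. With the upper 50% of each list, lost and gained regions numbered 3598 and 691 for H3K4me1, 986 and 3491 for PU.1, 3066 and 329 for ATAC in Utx KO, 1555 and 201 for Smarca4 gRNA in WT, 1805 and 55 for Smarca4 gRNA in KO and 3304 and 6 for Chd4 gRNA, fewer by construction, and the ratio moved to 3.22 for ATAC in Utx KO and 9.11 for Chd4 gRNA. At equal list length they numbered 4013 and 2712 (ratio 0.57) for H3K4me1, 3716 and 3221 (ratio 0.21) for PU.1, 2985 and 2805 (ratio 0.0897) for ATAC in Utx KO, 1341 and 1145 (ratio 0.23) for Smarca4 gRNA in WT, 1268 and 715 (ratio 0.83) for Smarca4 gRNA in KO and 1171 and 834 (ratio 0.49) for Chd4 gRNA. Equal lists pull the ratio towards 0 by construction. When a library had to cover 50% of a region, PU.1 lost 4380 regions (ratio -0.0151), and the cause was not tested.

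Leaving out each library in turn eases the rule, so counts rise by construction. Lost regions then numbered 7299 to 13395 for H3K4me1, 2596 to 4795 for PU.1, 8566 to 11559 for ATAC in Utx KO, 4892 to 7371 for Smarca4 gRNA in WT, 4420 to 9459 for Smarca4 gRNA in KO and 7881 to 15554 for Chd4 gRNA. Gained regions numbered 1610 to 4438 for H3K4me1, 7039 to 12057 for PU.1, 1658 to 2367 for ATAC in Utx KO, 1021 to 3008 for Smarca4 gRNA in WT, 315 to 1827 for Smarca4 gRNA in KO and 102 to 985 for Chd4 gRNA. The ratio lay at 1.01 to 3.06 for H3K4me1, -2.22 to -0.55 for PU.1, 1.86 to 2.80 for ATAC in Utx KO, 0.70 to 2.85 for Smarca4 gRNA in WT, 1.41 to 4.49 for Smarca4 gRNA in KO and 3.0 to 7.25 for Chd4 gRNA. Gene list tests past the threshold numbered 1 to 3 for H3K4me1, 0 to 2 for PU.1, 0 to 1 for Smarca4 gRNA in each genotype and 0 for the other comparisons. The odds ratio for stem cell genes lay at 2.23 to 2.83 and that for B cell genes at 3.67 to 7.73.

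The stem cell loss of H3K4me1 missed the threshold with regions within 50 kb of a gene (odds ratio 2.18), at equal list length (2.31) and without Mllt3 (2.22), with fewer regions in the list each time. Over strata of score or width 4 H3K4me1 list tests passed, adding losses at erythroid genes (2.82, and 3.57 at equal list length) and megakaryocyte genes (3.72), and 1 each for PU.1 (B cell gain, 3.02) and ATAC in Utx KO (mast cell and basophil gain, 2.94). Within 50 kb of a gene 1 H3K4me1 test passed. Over strata of width the lower PU.1 share at ATAC regions lost in Utx KO missed the threshold (0.947 and 0.955 for PU.1 of WT and KO). That of H3K4me1 reversed to 1.53 and 1.24. The lower shares thus went with the narrower width of lost regions, and whether width was their cause was not tested. Over all settings, those named included, 1286 single-list values kept their call, 14 passed anew and 4 lost their call, 100 joins of PU.1 and H3K4me1 kept theirs, and 23 of the lost and 19 of the gained counts stayed within 1.5 times. Motif tests, with their windows, GC strata and promoter filter, were not run.

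ChIP samples of different groups share only a replicate number. Empty-vector and gRNA libraries share a name such as WT1, but whether that means the same cells is not stated, and the splits were counted without regard to it. Summed within same-numbered pairs (replicate block), the ratio was 1.34 for H3K4me1, 1.97 for ATAC in Utx KO, 1.45 for Smarca4 gRNA in WT, 2.09 for Smarca4 gRNA in KO and 4.15 for Chd4 gRNA, and that of PU.1 stayed negative. Deviations of same-numbered samples correlated at -0.0195 to 0.0413, and no PU.1 sample correlated best with its own number. Depth is known only as reads in islands, and a shorter list cannot be told from a shallower library.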

Other observations

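The tests across assays and the overlaps of Smarca4 and Chd4 losses were chosen only after the results were seen, 16 tests by Fisher's exact test or over strata. The strata were of peak width for ATAC regions and of island reads for PU.1 regions. PU.1 and H3K4me1 gains in Utx KO lay together: of PU.1 regions in gained H3K4me1 islands 193 of 849 (22.7%) against 2.21% in kept islands were themselves gained (odds ratio 13, 10.9 to 15.5; 9.79 over strata). PU.1 regions in lost islands were lost in 178 of 3134 (5.68%) against 1.5% (odds ratio 3.95, 3.31 to 4.68; 2.45 over strata). ATAC regions at gained PU.1 were gained in 16 of 235 (6.81%) against 1.22% at kept PU.1 (odds ratio 5.90, 3.27 to 9.97; 3.84 over strata). ATAC regions at gained H3K4me1 islands were gained in 5 of 129 (3.88%) against 1.07% (odds ratio 3.72, 1.18 to 9.03; 2.69 over strata). ATAC loss at lost PU.1, 41 of 176 (23.3%) against 13.4%, had an odds ratio of 1.96 and missed the threshold over strata of width (1.46). ATAC loss at lost H3K4me1 islands, 314 of 1205 (26.1%) against 15.0%, had an odds ratio of 2.0 that came to 1.04 over strata of width.

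Losses after Smarca4 gRNA overlapped between Utx genotypes, whose controls are separate. Of 32815 ATAC regions held by all empty-vector libraries of that set, 423 were lost in both genotypes, against 64.5 for independent lists (odds ratio 15.4, 13.2 to 17.9; 5.03 over strata of width). Chd4 and Smarca4 gRNA in Utx WT cells shared 177 lost regions of 25460, against 46.9 (odds ratio 5.44, 4.49 to 6.56; 2.66 over strata). Independent lists take every region as equally likely to be lost. All gRNA lists were shorter than their empty-vector lists, no unchanged groups were simulated here, and peak strength beyond width was not tested. These overlaps alone therefore do not show shared targets.

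Of the tests that follow, the log2 ratio at equal list length was planned; those of the X share, the B cell gain, the other splits and their equal list length were chosen only after the patterns were seen, though list length for the X share and a single gene for the B cell gain were set down before their own results.

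Regions on the X chromosome were gained in Utx KO more often than autosomal ones by Fisher's exact test, for PU.1 in 279 of 3620 (7.71% against 4.69% on autosomes, odds ratio 1.70, 1.49 to 1.93), for ATAC in 51 of 918 (5.56% against 3.12% on autosomes, odds ratio 1.83, 1.34 to 2.44) and for H3K4me1 in 36 of 600 (6.0% against 3.93% on autosomes, odds ratio 1.56, 1.08 to 2.20). X regions were lost in Utx KO less often for PU.1 (0.975% against 2.08%, odds ratio 0.463, 0.309 to 0.668) and ATAC (9.89% against 15.6%, 0.593, 0.475 to 0.735). For H3K4me1 losses the odds ratio was 0.930 (0.730 to 1.17). Regions are not independent replicates, so these intervals do not measure spread between libraries. Between libraries the X share had p = 0.10 for PU.1 and 0.333 for ATAC by exact permutation, each the smallest possible. After Smarca4 gRNA in WT cells 10 of 857 X regions were gained (1.17% against 1.42%, odds ratio 0.820, 0.389 to 1.53), without an excess. The 4 and 1 X regions gained after Smarca4 gRNA in KO cells and Chd4 gRNA are too few to compare. Genes with most X-linked PU.1 gains, named after their values were seen, were Diaph2 16 of 140 (chromosome X, 129749668 to 130465834), Pcdh19 7 of 36, Reps2 7 of 42 and Huwe1 6 of 26, and the gains lay in 17 of 18 windows of 10 Mb. List length is argued against, since at equal length the lowest KO share exceeded the highest WT share by 0.163 percentage points for PU.1 and 0.295 for ATAC, and by 0.129 for H3K4me1, whose whole lists overlapped. No sign of male cells in the WT samples was seen, with 0 peaks at 4 Y genes in the PU.1 and 0 in the ATAC libraries. However, no library of the series held a peak there, so it is not shown that male cells would give a peak. Male cells thus stay open. For PU.1 and ATAC, X lay 4.99 and 4.65 SDs of the autosomes above the highest autosome. Gene density did not enter that test, so it cannot decide on a shift of gene-poor chromosomes. X copy number stays open, as the ChIP lists give reads within islands only and the ATAC lists none. The PU.1 libraries held 5 to 9 peaks at the X-inactivation gene Xist and the empty-vector ATAC libraries 2 or 3, which does not count X copies. Beside it stays the hypothesis that loss of Utx, itself X-linked, could open X chromatin. Deletion of Utx in cells of known X copy number would decide.

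H3K4me1 gains at B cell genes went with immunoglobulin light chain loci: islands over Igk (chromosome 6, 67555636 to 70726754) numbered 6 and 6 in WT against 20 and 26 in KO libraries, and PU.1 islands 30, 28 and 23 against 74, 60 and 64. Igl held 0 and 0 against 2 and 4 H3K4me1 islands, whereas the heavy chain locus Igh held 18 and 38 against 25 and 19. A single gene is argued against, as the list without Ebf1 kept an adjusted p = 0.00337 by Fisher's exact test. More B lineage cells in the KO fraction stay open: over all immunoglobulin loci the lowest KO library exceeded the highest WT library by 3 islands, and the only gate the labels name is a lineage depletion kit, a step meant to remove B cells whose yield no value here shows. Opening of B cell genes in the progenitors themselves may equally underlie it, and ATAC libraries from cultured cells, with 0 to 5 Igk peaks each, do not decide, as sorted cells would.

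ATAC regions such as those at Cmip in Utx KO and at Sox6 after Chd4 gRNA were lost more often than others were gained. At equal list length the log2 ratio was 0.0897 in Utx KO, 0.23 and 0.83 after Smarca4 gRNA in WT and KO cells and 0.49 after Chd4 gRNA, but equal lists pull it towards 0 whatever the cause and what is left has no spread, so list length and a true excess of losses cannot be told apart. List length alone is argued against as the source of the differing regions in Utx KO, with 7.02 times the highest other split at equal length, and after Smarca4 gRNA in KO cells, with 2.24 times. It stays open for Smarca4 gRNA in KO cells (2.24 times) and WT cells (1.55 times) and for Chd4 gRNA (1.83 times). No limit for these multiples was set before the patterns were seen, and each comparison has only 3 splits. Trimming by width does not equalise depth, so depth stays open in all of them. A hypothesis is that remodellers and Utx mostly keep chromatin open, and unequal depth could give the same direction; read counts per region scaled for depth would decide.

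For PU.1, 7961 regions were lost or gained and the highest other split gave 1514. Only 1 of 10 splits of these libraries, the real one, reached that number, and so few splits cannot give a share under 0.05. Without KO replicate 2, 12057 were gained, and without WT replicate 1, WT replicate 3 and KO replicate 1, 3530, 3809 and 4795 were lost.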
